A study of Homo sapiens and Drosophila melanogaster and Mus musculus with 12 samples.

How the data were processed

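GRID-seq libraries from MDA-MB-231, MM.1S, mouse embryonic stem cells and Drosophila S2 cells (2 each, 8 in all) and GRO-seq libraries from MDA-MB-231 cells under JQ1 or DMSO (2 each, 4 in all) were used. Per the labels' protocols, cells were fixed with DSG and formaldehyde, nuclei were digested with AluI, RNA and DNA were ligated to a linker in place, and MmeI released paired tags for sequencing. The series' own description speaks of 3 cell types of 3 species, and the samples hold 4 cell types of 3 species. Per the submitters' processing notes, Bowtie2, MACS2, bedtools and SAMtools were used, with no versions or settings, on the builds hg38 (GRCh38), mm9 and dm3 (BDGP5). All coordinates are given in these builds as the deposited tables hold them, 1-based.

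The deposited GRO-seq table holds RPM (reads scaled to 1e+06 total reads) per library for 27003 human genes, per the file headers and the values. The part of each gene that was counted and the strand handling are not stated beyond words that name a 2 kb gene part and a 2 kb mask, so overlapping and antisense genes cannot be told apart. Each library's values are whole multiples of its smallest value (100% of values within 0.01 read), which gives the reads behind them and total depths of 7246752, 9526068, 8413940 and 10318928 reads. One read is worth 0.138, 0.105, 0.119 and 0.0969 RPM in these libraries, and 2.12%, 2.15%, 2.03% and 2.03% of the reads lay on counted gene parts. Intervals and floors cover counting error only. In 8474 genes all 4 libraries are listed at 0, ACTB among them, while GAPDH has between 39.1 and 49.8 RPM. The authors also deposited the sum of both libraries per group in RPM and the log2 ratio of these sums, each plus 1; both matched the library values in 100% of genes, and these columns were not tested. For example, the authors' log2 ratio was 0.48 for MALAT1 and 1.27 for BRD2.

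The deposited GRID-seq tables list 1 link per RNA and 1 kb DNA bin. For mouse and fly libraries and all merged tables, the deposited value behaves as a linear signal. In the merged MDA-MB-231 table it is scaled inversely to a whole number given per RNA: the product of this number and the RNA's smallest value spans 1.02-fold from the 5th to the 95th percentile, where the number spans 16.3-fold. The product spans 2.67-fold in MM.1S, 4.54-fold in S2 and 23.0-fold in stem cells, so this scaling is not shown for stem cells. For the single human libraries, the deposited value is a score on a compressed scale from 1 to about 11.8. These readings of the signal and the score come from the values, as the tables have no header. Only links above a limit are listed: 2 in the human merged tables, 1 in the human libraries and 0.02 in mouse and fly tables. The whole number per RNA is the same in both libraries of a cell type and is called the pooled number here. Read depth is unknown for these libraries, so no counting intervals are given. Gene names came from the human name table and biotypes from the RefSeq table given for hg38: 26503 GRO-seq genes (98.1%), 949 of 973 MDA-MB-231 RNAs and 1055 of 1089 MM.1S RNAs had a symbol, and 0 of 2231 mouse and 0 of 724 fly RNAs. Marker lists for the mouse and fly cells were therefore not used here.

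The JQ1 comparison used limma 3.58.1 in R 4.3.3 with a trend on log2(RPM + 0.119), the pseudocount being the 10th percentile of values above 0. Genes with a mean under 0.0987 RPM, the 25th percentile of genes above 0, were left out, which kept 13915. Counts had been planned for if the table held them. As it holds RPM the test set out for normalised values was used, and edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads were added after the data were seen. limma called 9.54% of tested genes; called genes had a median of 55 reads over 4 libraries, tested genes 26. Gene lists were tested with camera (preset correlation), camera with an estimated correlation and fry, with Benjamini-Hochberg adjustment over lists. With an estimated correlation and 2 libraries per group, camera has few degrees of freedom. A failure there does not show that the members of a list are correlated. The human lines were compared with limma on log2 of the summed score scaled to 1e+06 plus 1, over 1628 RNAs listed in both libraries of at least 1 line. Distance shares, numbers of bins and overlaps are descriptive. An RNA was called broad with at least 50% of its value on other chromosomes and at least 10 chromosomes (4 in the fly) in both libraries. The relation between contact and JQ1 response used 2-sided permutation tests with 100000 permutations (10000 for alternatives). Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.

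Sample groups, tests, the 15 lists of the JQ1 comparison, those of the lines, the alternative settings not said to be added and the rule for named genes were set before the data were examined. The rule takes the 10 largest increases and decreases among called genes above the median level whose groups do not overlap, up to 4 members of each list with the smallest adjusted p, and, per cell type, the 10 RNAs with the largest share of contact value, the 10 with the most bins on other chromosomes and the chromatin RNAs. Of those, the text names the ones that describe each group. Replicate numbers were not used as pairs.

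Each test was checked on simulated data. For the JQ1 comparison, with 200 changed genes among 13865 with levels above the median seeded, limma called 47 of 50 genes raised 4-fold, 11 of 50 raised 2-fold, 4 of 50 lowered to 0.5 and 19 of 50 lowered to 0.25, and 6 of 87 calls were unchanged genes. With the changed genes seeded among all 13894 tested genes, these numbers were 35, 10, 2 and 16 of 50, and 4 of 67 calls were unchanged genes. For the JQ1 gene lists on 13859 simulated genes, a list of 20 members raised 1.5-fold had a camera adjusted p = 7.32e-11 and 0 of the other lists were called. In both JQ1 simulations genes were drawn independently with 1 common dispersion (0.00339). They therefore do not check lists with correlated members or genes that differ in their spread. For the human lines, the simulation used the 366 RNAs listed in all 4 libraries, so it does not cover RNAs listed in 1 line alone. There, 49 of 50 RNAs raised 1.5-fold were called and 11 of 209 calls were unchanged. For the relation with contact on 925 simulated genes, a true correlation of 0.5 gave 0.473 and one of 0 gave 0.0294 (permutation p = 0.361). Decreases are thus called less often than increases of the same size in the JQ1 comparison.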

Results

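Contacts between RNA and chromatin were measured with GRID-seq in 4 kinds of cultured cells: MDA-MB-231 (a human triple-negative breast cancer line), MM.1S (a human multiple myeloma line), mouse embryonic stem cells and Drosophila S2 cells. GRID-seq joins RNA to nearby genomic DNA with a linker inside fixed nuclei, so each link pairs an RNA with a DNA position. Nascent transcription was measured with GRO-seq in MDA-MB-231 cells treated for 6 h with 500 nM JQ1, an inhibitor of the BET bromodomain proteins, or with 0.05% DMSO as vehicle. Each of the 6 groups had 2 libraries, 12 in all, and the labels do not say whether these are separate cultures or technical repeats. The GRO-seq values imply 7246752 and 9526068 total reads in the DMSO libraries and 8413940 and 10318928 in the JQ1 libraries, of which 153977, 205241, 171006 and 209388 lay on the counted parts of genes. The GRID-seq tables give no read totals. They list 2909691 and 2627980 links between an RNA and a 1 kb DNA bin for MDA-MB-231, 1978168 and 2059229 for MM.1S, 5162459 and 3822178 for mouse stem cells, and 320038 and 112768 for S2. These links belong to between 959 and 966 RNAs in the MDA-MB-231 libraries, 1076 and 1079 in MM.1S, 2224 and 2226 in the stem cells, and 696 and 710 in S2.

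The first comparison asked which genes change their transcription when BET proteins are blocked in MDA-MB-231 cells. Of 15 gene lists fixed beforehand, 10 passed camera, limma's competitive list test, and 0 of them passed with an estimated correlation. That setting has few degrees of freedom with 2 libraries per group. The mitotic list failed it at an estimated correlation of −0.0216, so failing alone does not show that correlated members account for a list. Estimated correlations were higher for sterol synthesis (0.313), immediate early (0.176) and ribosomal protein genes (0.137), so the mitotic value does not speak for these lists. With fry, 7 of the 10 lists passed. The sterol synthesis, immediate early and BET feedback lists did not (fry adjusted p = 0.107, 0.0855 and 0.191). Of the lists past camera, those with lower values in JQ1 hold mitotic, DNA replication, ribosome biogenesis, ribosomal protein and matrix genes. Those with higher values hold histone, sterol synthesis, lysosome and autophagy, immediate early and BET feedback genes. The cell cycle inhibitor CDKN1A rose from 1.36 ± 0.16 to 14.1 ± 1.35 RPM (reads scaled to 1e+06 total reads; mean ± SD, n = 2), and the autophagy receptor SQSTM1 from 7.49 ± 0.84 to 33.0 ± 0.09. The urokinase gene PLAU fell from 26.3 ± 0.67 to 3.57 ± 1.52 RPM. Of 13915 genes tested with limma, 463 were higher and 865 lower in JQ1 at a Benjamini-Hochberg adjusted p under 0.05, and 401 of the higher and 745 of the lower ones had changed at least 2-fold. At an unadjusted p under 0.05, 1298 were higher and 2210 lower. Both JQ1 libraries lay on the same side of both DMSO libraries for 7413 of the tested genes, where chance gives 33.3%. With any single library left out limma called 0 genes, with 926 higher and 1198 lower at an unadjusted p under 0.05 without DMSO library 1, 1230 and 1195 without DMSO library 2, 669 and 1457 without JQ1 library 1, and 592 and 1600 without JQ1 library 2. Scaling the libraries to the same median moved the median log2 fold change from −0.13 to 0.01 and the calls to 831 higher and 790 lower (51.3% higher against 34.9%), limma without a trend called 0 genes (1085 higher and 1819 lower at an unadjusted p under 0.05), and on the recovered reads edgeR called 763 higher and 865 lower and DESeq2 106 and 85.

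Among the largest increases, ASNS, which makes asparagine, rose by a log2 fold change of 3.94 ± 0.31 (SE; adjusted p = 4.71e-08), from 0.417 to 8.13 RPM. SESN2, a stress-induced inhibitor of mTORC1 signalling, rose by 3.28 ± 0.38 (adjusted p = 1.10e-05), and CTH, which makes cysteine, by 3.15 ± 0.33 (adjusted p = 2.92e-06). CDKN1A rose by 3.27 ± 0.22 (adjusted p = 8.75e-09). ULK1, a kinase that starts autophagy, rose by 3.22 ± 0.62 (adjusted p = 0.00251). The histone genes H2BC21 and H2BC5 rose by 3.85 ± 0.27 and 3.83 ± 0.26. H2BC3 and H2BC4 carried identical values in all 4 libraries, 0.538 to 5.88 RPM, and the cause was not tested. ENSG00000259827, which has no symbol in the name table, had the largest increase, 4.56 ± 0.22, from 0.903 to 23.9 RPM.

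Among the largest decreases, CAV1, the main caveolar coat protein, fell from 3.21 ± 0.53 RPM to 0 reads in both JQ1 libraries, at least 20.1-fold lower when 3 reads over both libraries are taken as the floor. The cadherin family gene FAT3 fell by a log2 value of 3.94 ± 0.55 (adjusted p = 0.000126). CD74, the invariant chain of MHC class II, fell by 3.81 ± 0.56, and NSD1, a histone H3K36 methyltransferase, by 3.68 ± 0.58. CEMIP, which takes part in hyaluronan breakdown, fell by 3.39 ± 0.58, and CCDC9B by 3.37 ± 0.30. CCDC86 and RCSD1 were at 1.53 RPM in DMSO and at 0 reads in both JQ1 libraries, at least 9.55-fold and 9.53-fold lower.

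**Figure D1:**
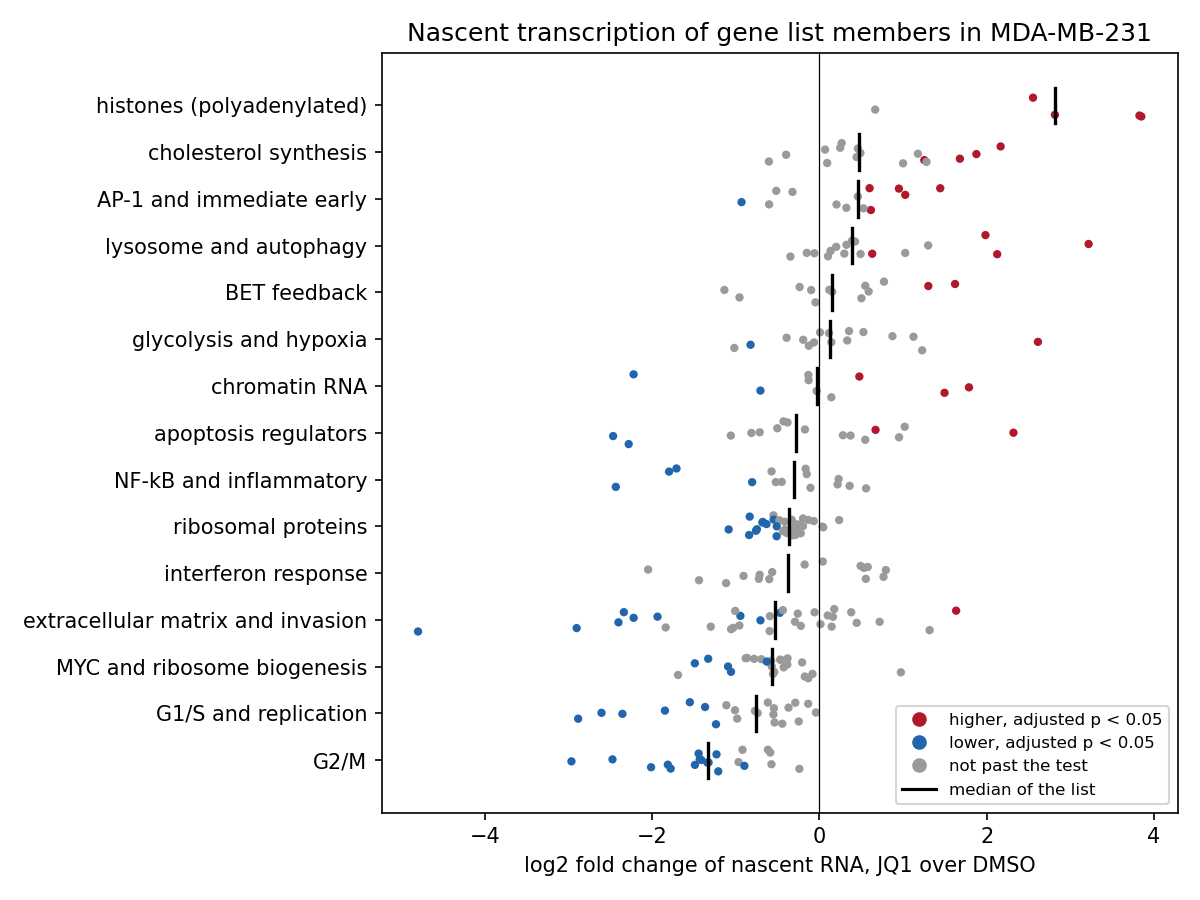
Log2 fold change of nascent RNA, JQ1 over DMSO (x axis), for the measured members of the 15 gene lists; each point is a gene, red and blue points passed limma's test, and black bars are list medians. On the raw log2 scale the medians run from −1.33 for the mitotic list to 2.82 for the histone list.

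In the cell cycle lists the calls were decreases. Of 20 mitotic (G2/M) genes, 14 fell (15 adjusted over the list alone) and 0 rose. Among them, the kinase AURKA went from 6.35 to 0.707 RPM, cyclin B1 (CCNB1) from 5.59 to 1.39, UBE2C, the ubiquitin-conjugating enzyme of the anaphase-promoting complex, from 11.6 to 4.15, while CDC20, an activator of that complex, fell by a log2 value of 1.41. The median of this list lay 1.20 below that of all genes, a log2 difference of −1.20, and list medians are given in this way unless called raw. Camera gave an adjusted p = 1.03e-13 (adjusted p = 0.122 with an estimated correlation). Of 22 G1/S and replication genes, 7 fell (10 adjusted over the list alone) and 0 rose, with a median of −0.63 (camera adjusted p = 1.51e-06; adjusted p = 0.145 with an estimated correlation). TYMS, which makes dTMP, went from 4.35 to 0.491 RPM, cyclin D1 (CCND1) from 8.53 to 2.89, and the replicative helicase subunit MCM3 from 2.50 to 0.313.

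In the lists of ribosome production the calls were also decreases. Of 24 genes in the list of MYC and ribosome biogenesis, 5 fell (11 adjusted over the list alone; 4 with the scaled libraries) and 0 rose, with a median of −0.43 (camera adjusted p = 2.83e-05; adjusted p = 0.145 with an estimated correlation). NOP16 fell by a log2 value of 1.49 ± 0.28, the pseudouridine synthase DKC1 by 1.06 ± 0.26 and the RNA acetyltransferase NAT10 by 1.09 ± 0.32. MYC itself went from 13.4 ± 0.90 to 8.72 ± 1.78 RPM (log2 fold change −0.63 ± 0.17, adjusted p = 0.0283), a call lost when libraries were scaled to the same median (adjusted p = 0.148). Of 34 ribosomal protein genes, 11 fell (14 adjusted over the list alone; 3 with the scaled libraries) and 0 rose, with a median of −0.24 (camera adjusted p = 1.03e-07; adjusted p = 0.236 with an estimated correlation). RPS19 went from 13.1 to 6.12 RPM and RPL37 from 16.7 to 9.26.

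The calls among matrix and inflammatory genes were mostly decreases. Of 32 genes of extracellular matrix and invasion, 9 fell and 1 rose (13 and 3 adjusted over the list alone), with a median of −0.40 (camera adjusted p = 0.000985; adjusted p = 0.145 with an estimated correlation). Besides PLAU and CAV1, THBS1, a secreted matrix glycoprotein, went from 42.3 to 21.9 RPM and CAV2 from 4.23 to 0.718. In the list of NF-kB and inflammatory genes 4 of 14 fell and 0 rose (the same counts adjusted over the list alone), with a median of −0.18 (camera adjusted p = 0.0919). These were LIF, from 5.31 to 0.874 RPM, IL6, from 13.1 to 7.45, TRAF1 and TNFAIP3. Of 16 interferon response genes, 0 passed limma's test in either direction over all genes or over the list alone (median −0.24, camera adjusted p = 0.786). The lowest adjusted p in that list was 0.0617, for IFI44.

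Among the lists that were higher, the histone genes moved furthest. Of the 5 measured members of the list named replication-independent and polyadenylated histones, 4 rose, also over the list alone, with a median of 2.94 (camera adjusted p = 2.63e-13, and 0.122 with an estimated correlation). GRO-seq does not show whether their RNAs are polyadenylated. H2AC6 went from 5.94 to 35.5 RPM and H2BC11 from 0.781 to 6.22. Of 16 cholesterol synthesis genes, 4 rose (6 adjusted over the list alone) and 0 fell, with a median of 0.60 (camera adjusted p = 0.000136; adjusted p = 0.274 with an estimated correlation). They were INSIG1, a sterol sensor, from 1.22 to 4.70 RPM, and the pathway enzymes IDI1, CYP51A1 and LSS. Of 17 lysosome and autophagy genes, 4 rose (6 adjusted over the list alone) and 0 fell, with a median of 0.52 (camera adjusted p = 4.23e-05; adjusted p = 0.145 with an estimated correlation). Besides SQSTM1 and ULK1, VMP1 went from 52.7 to 81.7 RPM and MAP1LC3B, which coats autophagosomes, from 0.541 to 1.96.

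Several regulatory lists held members that moved in both directions. In the list of AP-1 and immediate early genes 5 of 13 rose and 1 fell (6 and 3 adjusted over the list alone), with a median of 0.59 (camera adjusted p = 0.00938; adjusted p = 0.275 with an estimated correlation). The MAP kinase phosphatases DUSP6 and DUSP5 went from 29.9 to 58.0 and from 6.13 to 12.5 RPM, and the AP-1 subunit FOSL2 from 9.01 to 4.63. Of 13 genes in the list of BET feedback, 2 rose (3 adjusted over the list alone) and 0 fell, with a median of 0.28 (camera adjusted p = 0.0301; adjusted p = 0.274 with an estimated correlation). These were BRD2, itself a BET protein, from 12.4 ± 1.20 to 30.7 ± 0.33 RPM (adjusted p = 3.02e-06), and POLR2A, the largest subunit of RNA polymerase II, from 0.922 to 3.01. Of 16 glycolysis and hypoxia genes 1 rose, NDRG1 (0.226 to 1.96 RPM), and 1 fell, ENO1 (15.4 to 8.64); over the list alone these counts were 3 and 1 (median 0.26, camera adjusted p = 0.0562). Of 16 apoptosis regulators, 2 rose and 2 fell (2 and 3 adjusted over the list alone). The death receptor TNFRSF10B went from 1.27 to 6.78 RPM and MCL1 from 25.6 to 40.9, while CFLAR, an inhibitor of caspase-8, went from 3.08 to 0.469. The raw median of this list (−0.28) and its raw mean (−0.17) were below 0 and camera's direction was up (adjusted p = 0.673). Of 9 chromatin RNA genes, 3 rose and 2 fell, also over the list alone. The long nuclear RNAs NEAT1, MALAT1 and KCNQ1OT1 went from 57.5 to 163, from 139 to 193 and from 0.991 to 3.73 RPM, and PVT1 from 2.38 to 0.421. The raw median of this list was −0.03, its raw mean 0.08 and camera's direction up (adjusted p = 0.103).

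**Figure D2:**
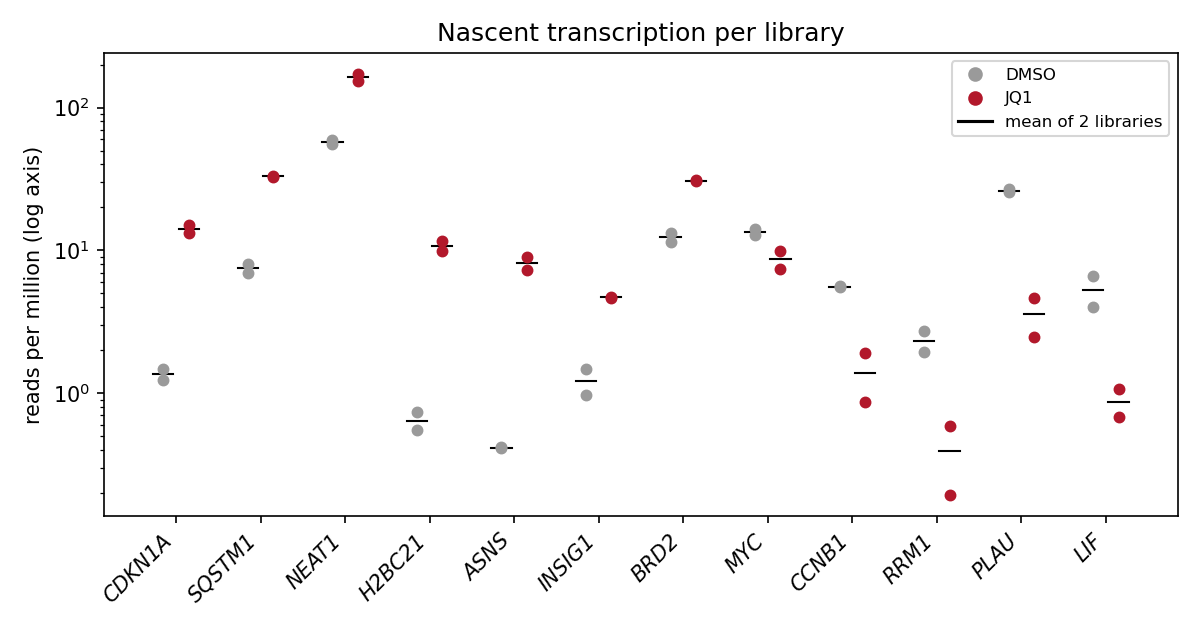
RPM (log axis) of 12 genes in each GRO-seq library, grey for DMSO and red for JQ1, with the mean of 2 libraries as a bar. CDKN1A rises from 1.36 to 14.1 RPM and PLAU falls from 26.3 to 3.57 RPM.

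The next comparison asked how far from its own gene each RNA was found on chromatin. In every library most of the listed contact value lay close to the RNA's gene. In MDA-MB-231, 59.8% ± 1.73 (mean ± SD, n = 2) lay within 1 Mb, and 11.4% ± 0.66 of all value lay on the gene itself. In MM.1S these shares were 71.0% ± 0.57 and 13.6% ± 0.31, and the difference between the lines in the share within 1 Mb was larger than the spread between libraries. In mouse stem cells 92.7% ± 1.48 lay within 1 Mb and 27.8% ± 1.66 on the gene, and in S2 98.6% ± 0.71 and 46.8% ± 8.46. Other chromosomes held 0.904% ± 0.114 in MDA-MB-231, 0.657% ± 0.0157 in MM.1S, 0.0553% ± 0.0148 in stem cells and 0.369% ± 0.195 in S2. The human libraries list a compressed score and the mouse and fly libraries a linear signal, so shares were compared between the human lines only. Even there, the number of listed links differed at the same limit of 1, and read depth is unknown. Whether this moves the share within 1 Mb was not tested. In the authors' merged tables, all in the linear signal, the shares within 1 Mb were 77.8%, 81.7%, 87.5% and 97.1% in the same order. Those on the gene itself were 29.1%, 27.4%, 23.7% and 40.1%, with the order of the human lines turned, and those on other chromosomes 1.19%, 0.587%, 0.136% and 1.09%. Across RNAs, which are not independent replicates, log2 sums of the paired libraries correlated with Pearson's r of 0.996 (955 RNAs, Spearman 0.998) in MDA-MB-231, 0.994 (1074, 0.998) in MM.1S, 0.992 (2220, 0.989) in stem cells and 0.952 (694, 0.927) in S2.

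**Figure D3:**
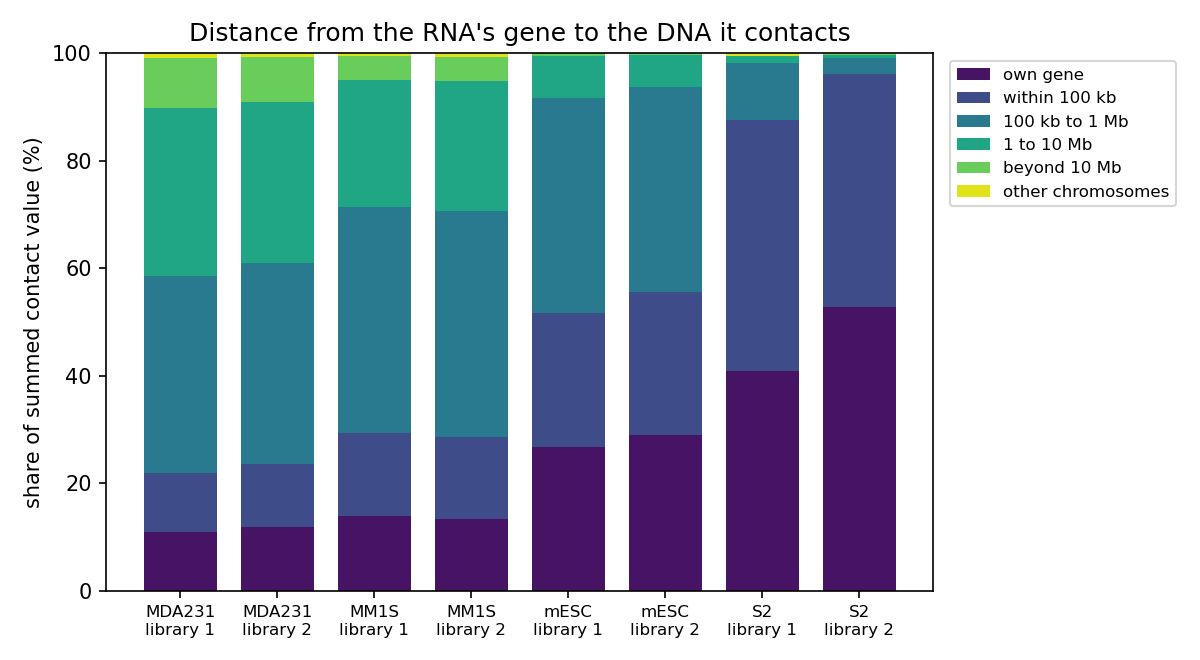
Share of each GRID-seq library's summed contact value (y axis, percent) by distance between the RNA's gene and the contacted DNA. Contacts within 1 Mb, the lower 3 colours, make up 59.8% on average in MDA-MB-231 and 98.6% in S2.

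A small set of RNAs was spread over the genome instead. In MDA-MB-231, 10 RNAs had at least 50% of their contact value on other chromosomes and reached at least 10 chromosomes in both libraries. They were RNAs of the spliceosomal U2 type (RNU2-2P, U2 and RNU2-36P, the last a pseudogene by its biotype), the nuclear speckle RNA MALAT1, 7SK, a regulator of transcription elongation, and its pseudogene RN7SKP160. Whether reads were split among similar U2 genes was not tested, so the U2 entries need not be separate RNAs. The RNA subunits of RNase P (RPPH1) and RNase MRP (RMRP) also qualified, each with an overlapping gene at almost the same position (ENSG00000259001 and ENSG00000269900). RNU2-36P was listed on 10725 and 10451 bins in the 2 libraries, 98.2% of its value in library 1 on other chromosomes. MALAT1 was listed on 9496 and 7522 bins, 74.3% and 71.6% of its value on other chromosomes. In MM.1S 5 RNAs were broad in both libraries: RNU2-2P, RNU2-36P, RNU5A-1, RNU5B-1 and ENSG00000278996 on chromosome 21. MALAT1 was listed on 560 and 711 bins there, 43.5% and 48.2% on other chromosomes, and NEAT1, the RNA of paraspeckles, on 5435 and 6197, 31.7% and 33.1% on other chromosomes. In the merged MM.1S table, 10 RNAs were broad, NEAT1 and MALAT1 among them. With only links above each library's median value 0 RNAs were broad in either line, because these RNAs carry low values per bin.

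By the compressed score of the single human libraries, the largest shares of the contact value belonged mostly to RNAs of protein-coding genes. In MDA-MB-231 the RNA of EXT1, which makes heparan sulphate chains (hg38 chromosome 8, 117794491 to 118111853), was listed on 46873 and 43215 bins and held 1.02% of the value of library 1. It was followed by EFNA5, MAML2, the long noncoding RNA LINC02742, MAGI1, SMYD3, PTPRG, CRIM1, KCNQ5 and ROR1. In MM.1S the largest shares belonged to NAV2 (0.828%), MAML2 (0.681%) and CDK14 (0.635%). In the linear signal of the merged tables the shares were smaller and the order differed: RNU2-2P (0.329%) lay above EXT1 (0.256%) in MDA-MB-231, and MAML2 (0.262%) and CDK14 (0.257%) above NAV2 (0.238%) in MM.1S. Protein-coding genes made up 851 (87.5%) of the RNAs in MDA-MB-231 and 952 (87.4%) in MM.1S.

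In mouse stem cells 3 RNAs were broad in both libraries. Tx.320, a transcript named by the authors (mm9 chromosome 17, 39979946 to 39985852), was listed on 77649 and 35198 bins, 99.7% and 99.5% of its value on other chromosomes. It was not spread evenly, as 97.9% and 99.2% of its bins on other chromosomes lay on chromosomes 12, 15, 16, 18 and 19. Its gene lies in a stretch where a sequence of many copies may have been placed at 1 position, so its call as broad is uncertain. ENSMUSG00000092341 (chromosome 19, 5795691 to 5802671) was listed on 44660 and 19895 bins, 81.3% and 73.4% on other chromosomes. In S2, 10 RNAs were broad in both libraries with a minimum of 4 chromosomes. The files do not pair mouse and fly identifiers with names. Without library 2 the counts were 6 in stem cells and 17 in S2, and 9 and 30 in the merged tables.

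**Figure D4:**
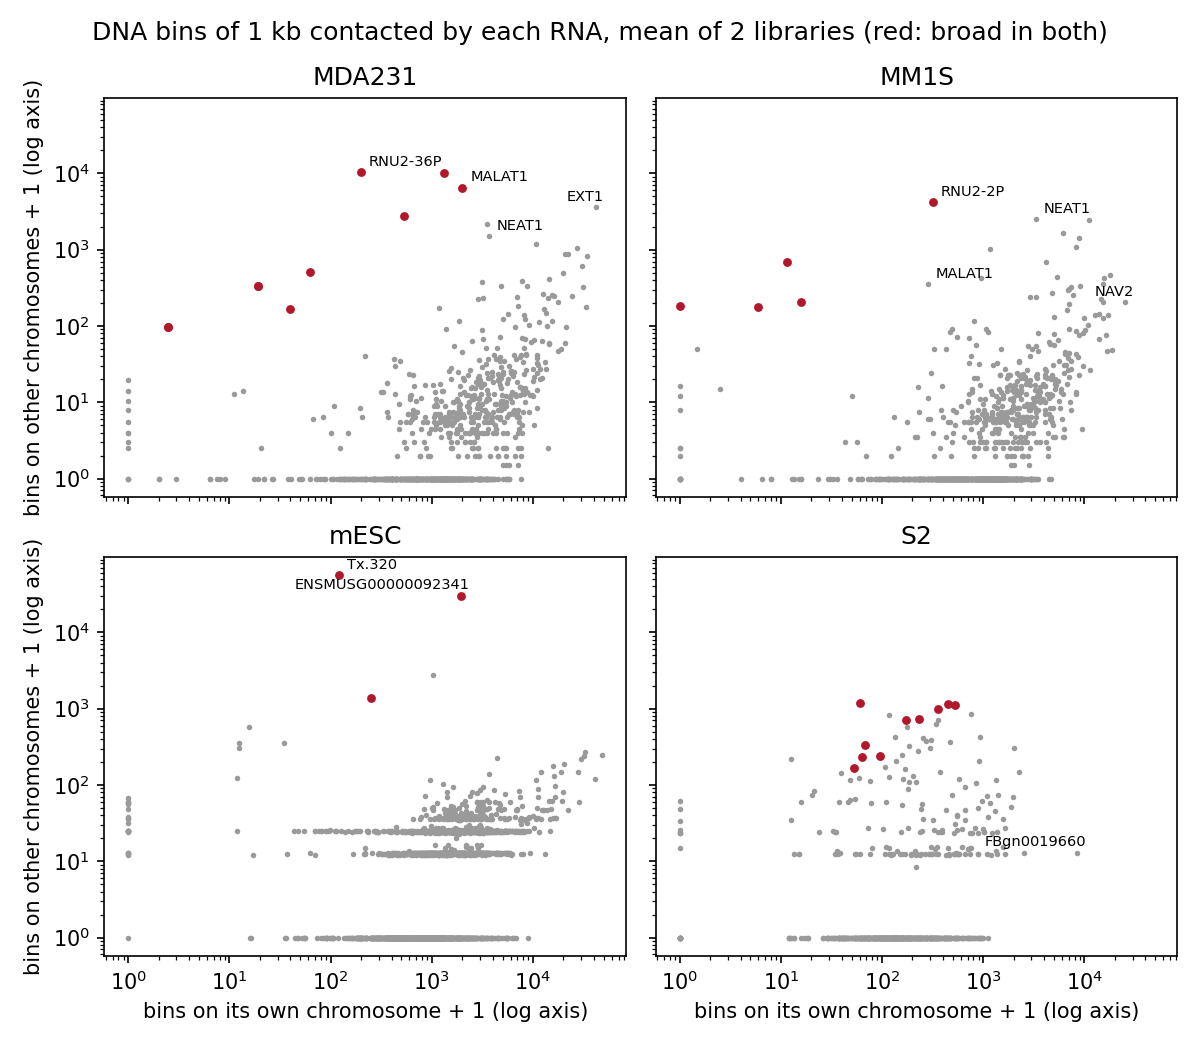
For each RNA, the number of 1 kb DNA bins on its own chromosome (x axis) and on other chromosomes (y axis), each plus 1 and as the mean of 2 libraries, on log axes. Red points are RNAs called broad in both libraries: 10 in MDA-MB-231 (2 pairs at almost the same position), 5 in MM.1S, 3 in mouse stem cells and 10 in S2.

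The S2 data address the dosage compensation of the male X chromosome, in which the roX RNAs take part. The files do not pair fly identifiers with names, so which identifiers are roX RNAs cannot be said from them, and no value is given under that name. The RNA on the most bins in S2 was followed, chosen after its values were seen. Whether it is itself a roX RNA cannot be said from the files. This RNA, FBgn0019660 (dm3 chromosome X, 11473090 to 11474465), was listed on 9535 and 7500 bins, where the next RNA had 3978 and 1051. Of its contact value, 99.9% in library 1 and 100% in library 2 lay on X, and it was on 59.5% and 65.4% of all listed X bins. The RNAs of genes on other chromosomes had 0.0244% ± 0.00843 of their value on X. For its bins over 1 Mb from its own gene, the share on X was 99.9% in library 1 and 100% in library 2, against 50.1% and 6.30% for the distant contacts of other X genes' RNAs.

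The comparison of the human lines asked which RNAs reach chromatin in breast cancer and in myeloma cells. Most measured RNAs of the matrix list and of the basal and mesenchymal list were higher in MDA-MB-231, and those of the plasma cell list in MM.1S. These 3 lists passed camera, and 0 of them passed with an estimated correlation. The plasma cell list failed that setting, which has few degrees of freedom here, at an estimated correlation of −0.0390. Most called RNAs of the 3 lists were listed in 1 line alone, so these calls follow from the listing. Of 22 measured genes of the plasma cell and myeloma list all 22 were higher in MM.1S, also adjusted over the list alone, 21 of them listed in MM.1S alone (camera adjusted p = 0.000411; adjusted p = 0.176 with an estimated correlation). They included the lymphoid transcription factor IKZF3, cyclin D2 (CCND2), the signal peptidase subunit SEC11C and HERPUD1, with 1090, 898, 344 and 542 parts in 1e+06 of the summed score in MM.1S and 0 in MDA-MB-231. Of 14 genes of extracellular matrix and invasion, 12 were higher in MDA-MB-231 and 1 lower (13 and 1 adjusted over the list alone; camera adjusted p = 0.00144; adjusted p = 0.176 with an estimated correlation). All 12 were listed in MDA-MB-231 alone, among them EGFR (5336), LAMC1 (802) and CAV1 (596). Of 12 basal and mesenchymal genes, 10 were higher and 1 lower (11 and 1 adjusted over the list alone; camera adjusted p = 0.00269; adjusted p = 0.176 with an estimated correlation), with RUNX1 at 2713 and the Hippo pathway factor YAP1 at 1634 against 0. Genes of the unfolded protein response and secretion were mostly higher in MM.1S, 7 of 8, with 1 higher in MDA-MB-231, also adjusted over the list alone. These included the chaperone HSP90B1 and the stress sensors ERN1 and ATF6, and the list did not pass camera (adjusted p = 0.126).

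Lists shared by both lines gave mixed results. Of 11 ribosomal protein RNAs, 6 were higher and 3 lower in MDA-MB-231 (camera adjusted p = 0.468), of 5 AP-1 and immediate early RNAs 4 were higher and 1 lower (adjusted p = 0.195), and of 15 chromatin RNAs 6 were higher and 8 lower (adjusted p = 0.999), with the same counts over each list alone. DUSP4 RNA was higher in MDA-MB-231 (log2 fold change 0.91) and DUSP5 RNA higher in MM.1S (−1.41). The interferon list had 1 listed RNA, IRF1, the NF-kB list 2, NFKB1 and TNFAIP3, and the luminal list 1, XBP1, all in MM.1S alone. The B cell, T and NK cell and myeloid lists had 0 listed RNAs in either line.

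Over all RNAs, limma called 664 higher in MDA-MB-231 and 895 higher in MM.1S of 1628 tested. Of these 1628, 577 were listed in MDA-MB-231 alone, 682 in MM.1S alone and 369 in both. All 577 of the first and 681 of the second were called, so these calls restate the listing and are not separate evidence. Among the 369 listed in both, 87 were called higher in MDA-MB-231 and 214 in MM.1S. Among the RNAs listed in 1 line alone, EXT1 (10343 parts in 1e+06), EFNA5 (9039) and LINC02742 (8757) had the largest sums in MDA-MB-231. CDK14 (6539), SETBP1 (6111), CELF2 (6074) and BCL2 (5469), the apoptosis inhibitor, had the largest in MM.1S. Of the 366 RNAs listed in all 4 libraries, 90 were higher in MDA-MB-231 and 211 in MM.1S. The protein disulphide isomerase TXNDC5 had the lowest log2 fold change, −3.30 ± 0.05 (SE), and CCNL1, a cyclin of RNA processing, −2.11 ± 0.09. RNU2-36P was at 5.02 ± 0.10, KLF6 at 1.29 ± 0.08 and MALAT1 at 3.21 ± 0.09. RNU2-2P, also of the U2 type, went the other way from RNU2-36P, with 0.0485% of the value in MDA-MB-231 and 0.0890% in MM.1S. Its pooled number was 1550939 in MDA-MB-231 and 160135 in MM.1S. How the listing limit acts on U2 RNAs was not tested, so 5.02 is not shown to be a difference in U2 RNA. The direction for MALAT1 is uncertain, since its lowest listed bin in the merged tables held 3.11 value steps in MDA-MB-231 and 31.5 or 11.8 in MM.1S. Its ratio of bins, MDA-MB-231 over MM.1S, was 7.74 as listed and 0.0053 or 0.198 at equal numbers of value steps. That test was chosen after the result was seen, and its limit could only lower the ratio. Summed score measures how many bins an RNA is listed on and how strongly, not its abundance, and an RNA under the listing limit counts as 0. Scaling the libraries to the same median moved the median log2 fold change from −0.43 to 0.18 and the calls to 820 and 745 (52.4% higher in MDA-MB-231 against 42.6%), turned the sign of 125 calls, and left 1 of the 22 plasma cell genes higher in MDA-MB-231 and 0 of the 14 matrix genes lower there. Bins on other chromosomes alone gave 185 and 173 calls.

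Seen from the DNA side, most bins were touched by few RNAs. The mean number of RNAs per listed bin was 1.97 and 1.88 in the MDA-MB-231 libraries and 1.70 and 1.73 in MM.1S. The highest was 19 in MDA-MB-231, on chromosome 11 at 125079001 and on chromosome 6 at 41072001, and 17 in MM.1S, on chromosome 1 at 156155001. In mouse stem cells the means were 2.71 and 2.25, with up to 1141 RNAs on single bins of chromosome 17. In S2 they were 3.37 and 1.81, with at most 28 and 9. The lines differed in which links they held. For RNAs listed in both lines, 54.9% of the links to bins were shared by the MDA-MB-231 libraries (Jaccard index), 52.4% by the MM.1S libraries, and 38.0% (37.6% to 38.4% over 4 pairs) by libraries of different lines. For listed bins regardless of RNA the values were 75.9%, 71.2% and 42.4%. Of the RNAs with human identifiers, 372 were listed in both lines, 591 in MDA-MB-231 alone and 692 in MM.1S alone.

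The last comparison asked whether genes whose RNA reaches far over chromatin respond differently to JQ1 in MDA-MB-231. Genes with a listed RNA were transcribed at a median of 2.64 RPM in DMSO, those without at 0.696 RPM. Of 925 listed genes, 54 rose and 171 fell, and of 12990 unlisted ones 409 rose and 694 fell. The median log2 fold change was −0.26 in listed and −0.12 in unlisted genes, a difference of −0.14 (2-sided permutation p = 1.00e-04, adjusted p = 0.00015 over 3 relations). Across listed genes, which are not independent replicates, the number of bins over 1 Mb away or on other chromosomes went with a lower fold change (Spearman's rho −0.132, permutation p = 9.00e-05, adjusted p = 0.00015). The medians from the lowest to the highest quartile of distant bins were −0.11, −0.24, −0.30 and −0.43, while the share of genes called lower was 18.1%, 19.5%, 14.7% and 21.6% and that called higher 6.47%, 4.76%, 6.49% and 5.63%, without such an order. The number of RNAs on the bin of a gene's start did not pass (1504 genes, rho −0.032, permutation p = 0.215), though it did in the authors' merged table (rho −0.051, permutation p = 0.0471). Examples with many RNAs at their start were ANKRD1 (15 RNAs, log2 fold change 0.57), BRD2 (12, 1.30) and LAMB3 (11, −2.26), chosen after their values were seen.

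The difference between listed and unlisted genes turned with the way level was held constant. Within quartiles of DMSO level, which is also the denominator of the fold change, the listed genes lay above the unlisted ones, by 0.24 (2-sided permutation p = 0.541, 8 listed genes), 0.44 (permutation p = 0.0328), 0.15 (p = 0.0313) and 0.0020 (p = 0.96). Within quartiles of the mean over all 4 libraries, chosen after seeing the data, the difference was 0.63 (permutation p = 0.164), −0.83 (p = 1.00e-04, the smallest possible with 10000 permutations), −0.32 (p = 1.00e-04) and −0.12 (p = 0.001). For distant bins, rho within DMSO quartiles was −0.135 (permutation p = 0.0387), −0.204 (p = 0.0018), −0.158 (p = 0.0196) and −0.111 (p = 0.0889). Within quartiles of the mean over all 4 libraries it was −0.083, 0.015, −0.196 and 0.028, with permutation p of 0.21, 0.827, 0.0027 and 0.668. Within quartiles of gene length, also chosen after seeing the data, it was −0.021, −0.108, −0.032 and −0.100, with permutation p of 0.749, 0.0989, 0.629 and 0.132, and gene length itself had a rho of 0.867 with distant bins and of −0.139 with the JQ1 fold change (permutation p = 0.0003).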

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

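Tests with edgeR, DESeq2, RNAs listed in all 4 libraries, numbers of bins for the lines, the gene's own RNA left out, gene length, the mean over all 4 libraries, lists without single libraries and the widest S2 RNA were chosen after the results were seen, and all others before. Where a value changed, the cause was not tested unless stated. Of 76 named JQ1 genes 68 were called, and all 68 lost their call when any 1 library was left out (an arm of 1 library is then assumed to vary like the other), all with the same direction.

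JQ1 gene counts. The calls went from 463 higher and 865 lower to 0 and 0 (lowest 0, highest 0) without each library in turn, to 831 higher with libraries scaled to the same median, to 0 and 0 in limma without a trend (1085 and 1819 at an unadjusted p under 0.05), to 230 and 449 with a pseudocount 4 times smaller, to 763 higher by edgeR and to 106 and 85 by DESeq2. No call changed sign under any of these. The replicate block gave 677 and 1234 calls, and 12 lists past camera instead of 10, and for the lines 668 and 897 calls and 3 lists. Deviations of libraries with the same number correlated at 0.0155 in GRO-seq and at −0.00638 in GRID-seq over 2 pairs. Such low values show no sign of pairing by number but cannot exclude it, as noise between libraries could hide it. Of the 10 lists that passed camera, 0 passed with an estimated correlation, a setting with few degrees of freedom here, and 7 passed with fry. Between 7 and 10 lists passed without each library in turn. Over all named genes and lists of both comparisons, 1258 values kept their side of the threshold, 398 lost it, 20 gained it and 0 reversed.

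Lines. The calls went from 664 and 895 to 356 and 440 with a stricter filter, to 185 and 173 over bins on other chromosomes and to 90 and 211 for RNAs listed in all 4 libraries, the first and last of these testing fewer RNAs. Libraries scaled to the same median turned the sign of 125 of the calls and bins on other chromosomes that of 58. Of the 3 lists that passed camera, 0 passed with an estimated correlation, a setting with few degrees of freedom here, while fry passed 7.

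Contact distance. The share within the window, in the order MDA-MB-231, MM.1S, stem cells and S2, was 22.8%, 28.9%, 53.6% and 91.8% at 100 kb and 90.4%, 94.9%, 99.5% and 99.6% at 10 Mb, as a smaller or larger window must give. It was 77.8%, 81.7%, 87.5% and 97.1% in the merged tables. Without the 10 RNAs with the largest sums it was 63.1% in MDA-MB-231 and 73.9% in MM.1S. Without each replicate it stayed between 58.5% and 61.0%, 70.6% and 71.4%, 91.7% and 93.8%, and 98.1% and 99.1%. Agreement of replicates in the upper 50% of yield was 0.998, 0.997, 0.977 and 0.698.

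Broad RNAs. Links above the library median left 0 in each of the 4 cell types. At 75% of the value 1 was left in stem cells and 3 in S2. The merged tables gave 10 in MM.1S, 9 in stem cells and 30 in S2. Without each replicate the counts ran from 3 to 6 in stem cells and from 10 to 17 in S2. Link overlap within MDA-MB-231, between lines and within MM.1S was 60.5%, 46.4% and 58.4% for links above the median and 53.2%, 35.9% and 50.9% in 10 kb bins, lowest between lines each time. The share on X of the widest S2 RNA was 99.9% by number of bins, 99.9% in the merged table and between 99.9% and 100% without each replicate.

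JQ1 response and contact. The relation with RNAs at the gene start passed in the merged table (rho −0.051, p = 0.0471) and in 0 of its other settings. For distant bins, rho in DMSO quartiles 1 to 4 was −0.135 (permutation p = 0.0387), −0.204 (p = 0.0018), −0.158 (p = 0.0196) and −0.111 (p = 0.0889). In the quartiles of gene length, by permutation as throughout, it was −0.021, −0.108, −0.032 and −0.100, and in quartiles of the mean over 4 libraries it was −0.083 (permutation p = 0.21), 0.015 (permutation p = 0.827), −0.196 (permutation p = 0.0027) and 0.028 (permutation p = 0.668). Listed genes lay 0.24, 0.44, 0.15 and 0.0020 above unlisted ones in the DMSO quartiles, and 0.63 above in quartile 1 of the mean but below in quartiles 2 to 4 (−0.83, −0.32 and −0.12), so the direction depends on how level is held constant.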

Other observations

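Tests in this part were chosen after the results were seen, except the 1 on copies of the Tx.320 gene. Lists of stress genes written after the values were seen also passed camera with higher values in JQ1. With an estimated correlation, a setting with few degrees of freedom here, 0 of them passed. After ASNS, SESN2 and CTH had been seen to rise, a list of 26 measured amino acid response genes was written. Of these, 11 rose and 0 fell (12 and 1 adjusted over the list alone), with a raw median log2 fold change of 0.50 (camera adjusted p = 1.95e-07; adjusted p = 0.0989 with an estimated correlation). Without those 3 genes, 8 of 23 rose (adjusted p = 0.000179; adjusted p = 0.0989 with an estimated correlation). They include PSAT1, an enzyme of serine synthesis, from 0.919 to 3.23 RPM, the mitochondrial PEP carboxykinase PCK2, from 1.86 to 5.18, and the amino acid transporters SLC38A2, from 12.5 to 24.5, SLC7A5, by a log2 fold change of 1.13, and SLC7A11, from 1.55 to 3.47.

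An oxidative stress list, written after SQSTM1 was seen, had 7 of 15 genes higher and 0 lower (9 and 3 adjusted over the list alone; raw median 1.11; camera adjusted p = 5.66e-07; adjusted p = 0.0989 with an estimated correlation), and 6 of 14 higher without SQSTM1. Thioredoxin reductase 1 (TXNRD1) went from 4.38 to 13.9 RPM and ferritin heavy chain (FTH1) from 10.1 to 24.6. In a p53 response list 6 of 18 rose and 1 fell, also over the list alone (raw median 0.34; camera adjusted p = 0.00129; adjusted p = 0.109 with an estimated correlation). RRM2B went from 0.348 to 1.99 RPM and SESN1 from 0.138 to 1.19, AEN fell from 3.56 to 0.718, and MDM2 was at 1.28 in DMSO and 0.636 in JQ1 (adjusted p = 0.215). Without 5 of its genes, CDKN1A, TNFRSF10B, BBC3, BAX and FAS, 4 of 13 rose and 1 fell (camera adjusted p = 0.0381, and 0.159 with an estimated correlation). Of those left out, CDKN1A and TNFRSF10B were called higher and the others were not called. BAX and FAS had log2 fold changes of −0.43 and −0.50, so leaving these out favours a rise in the remaining genes. Of 9 heat shock genes 1 rose, HSP90AA1, from 14.7 to 30.6 RPM, and 0 fell (adjusted p = 0.00569; adjusted p = 0.114 with an estimated correlation). With libraries scaled to the same median, the raw list medians were 0.64 for the amino acid response, 1.25 for oxidative stress, 0.48 for p53 and 0.42 for heat shock.

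In each human line some RNAs contacted stretches of another chromosome densely. In MDA-MB-231 EXT1 RNA was on 1108 and 989 bins in 3 windows of 1 Mb on chromosome 2 between 85000001 and 89000000, where RNAs of PTK2, ASAP1 and EIF3H, also on chromosome 8, were found, and in MM.1S RNAs of MAF and of the neighbouring Tx.200 on chromosome 16 contacted chromosome 14 between 105000001 and 107000000. Reads shared between similar sequences would put the same window in both lines, but 0% of the 15 windows whose RNA was listed in both lines held at least 50% as many bins in the other line. Chromosome segments joined in the line are a candidate explanation: 44.3% of the 61 windows (27; 18 of 45 in MDA-MB-231 and 9 of 16 in MM.1S), with 37 windows of broad RNAs left out, were shared by an RNA of a gene nearby or answered from the other side, against 9.77% on average and 27.9% at most in 100 shuffles, but over both lines below the 50% set for this explanation. The MM.1S windows alone lie above 50%, no shuffles were made per line, and the explanation stays open. No karyotype was used here, and no biological explanation was tested.

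MALAT1 was listed on 229102 bins in the merged MDA-MB-231 table and 29607 in that of MM.1S, a ratio of 7.74, although its pooled number was lower in MDA-MB-231 (354719 against 861078). The listing limit on a value divided by the RNA's own number may account for this, since 1 link is worth less for an RNA with a larger number. The lowest listed bin held 3.11 value steps in MDA-MB-231 and 31.5 in MM.1S, or 11.8 with a larger step assumed for MM.1S. At 31.5 steps the ratio was 0.0053 and at 11.8 steps 0.198. As these limits keep all 29607 MM.1S bins, the ratio could only fall, so its size does not give a direction. The number of listed bins is therefore not comparable between lines for this RNA, and a difference in its reach between the cell types remains untested.

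Mouse stem cells had bins on chromosome 17 (39972001 to 39996000) contacted by RNAs of 1580 genes and on chromosome 11 (3022001 to 3109000) by 508 in the merged table. A sequence present in many copies but placed at 1 position may explain them: RNAs from the bin's own chromosome were at most 1.40 times as frequent as among all RNAs, whereas the contacts of most RNAs are local. The gene of Tx.320 lies in the first of these stretches. In the merged table, 75.5% of its 269064 bins on other chromosomes fell on chromosomes 12, 15, 16, 18 and 19. These chromosomes hold 20.6% of all listed bins outside chromosome 17. In libraries 1 and 2, 97.9% of 77508 and 99.2% of 35098 bins of Tx.320 on other chromosomes fell on them. Copies of its gene near the centromere end of these chromosomes could produce this. Its share in their first 20 Mb was 1.28 times that of all bins, between the bounds set beforehand, so the test does not decide whether such copies account for it. Contacts near such copies would be local to them, although counted here as lying on other chromosomes. Neither the mouse genome nor its repeats were searched here, and no biological explanation was tested.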
